A study of Mus musculus with 78 samples.

How the data were processed

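Total RNA and polysome RNA were sequenced from mouse CD8+ T cells in 2 experiments. The cells came from spleen and lymph node of C57BL/6J mice and were on day 3 of activation. In the nutrient experiment they spent 3 h in complete medium (Control) or in medium without arginine, branched-chain amino acids (BCAA), glucose, glutamine or methionine. In the drug experiment they spent 3 h with DMSO, halofuginone, Torin1 or 4EGI-1. Per the labels, each lysate gave 50 µL of input for total RNA and 400 µL for a 15 to 45% sucrose gradient of 15 fractions, and fractions 9 to 13 were pooled as polysome RNA. Every group held 3 numbered libraries, and the labels do not say whether the replicates were separate cultures or animals.

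The deposited table gave raw read counts per Ensembl gene, whole numbers with no normalization. The submitters' processing notes list Trimmomatic, FastQC, MultiQC, STAR, HTSeq and edgeR with the mouse build GRCm39, without versions, roles or the criterion by which genes were kept. The table held 14695 genes, of which 14246 carried a symbol and 449 only an identifier. It covered 60 of the 78 libraries in the labels. The other 18, from monosome fractions, were not analysed here. No gene coordinates or lengths were used. The protocol added 20 pg of luciferase RNA, but no entry of the table was a luciferase transcript, so scaling to a spike-in was not run. The labels call the drug libraries polyA RNA and the nutrient libraries total RNA, so the 2 experiments were never fitted together. A pair of drug polysome libraries, Torin1 replicate 3 and 4EGI-1 replicate 2, carry an R after the replicate number whose meaning the labels do not give. They were used like the others.

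Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with a minimum count of 10, libraries were scaled by TMM, and groups were compared by edgeR's quasi-likelihood F test. P-values were adjusted by the Benjamini-Hochberg method within each comparison and called at 0.05. Total RNA and polysome RNA were each fitted over all groups of an experiment. The numbers of genes tested were 12642 and 12417 in the nutrient experiment and 12535 and 12223 in the drug experiment. Translational efficiency (TE) was the interaction term of a model over both kinds of library, the polysome to total ratio in a condition against that ratio in its control, with 13072 and 12745 genes tested. TMM assumes that most genes do not change relative to one another, so every change is relative and a shift common to all genes is not seen. Standard errors of log2 fold changes were taken from the fold change and its F statistic, and levels are counts scaled to the library total times the TMM factor (CPM), except that summed histone levels, ranges of markers and shares of counts use the plain library total. Replicate numbers were not taken to pair libraries within a fraction, where correlations between residuals of libraries with the same number lay between -0.201 and 0.343. The means were 0.0353 and 0.0755 in total and polysome RNA of the nutrient experiment, and 0.0776 and 0.0584 in the drug experiment. With the replicate number as a block, calls without arginine were 1512 (total RNA) and 5683 (polysome RNA), where the fit gave 1168 and 5034. In total RNA the block gave 4097 calls with Torin1 and 3151 with 4EGI-1, where the fit gave 3343 and 3308. Total and polysome libraries of 1 lysate are paired by design. Their residuals correlated at a mean of 0.0552 in the nutrient experiment (-0.0275 for other pairs) and 0.107, up to 0.308, in the drug experiment (-0.0533). Residuals were centred on the group mean, so the values for other pairs follow from those for paired libraries and are no separate evidence. The TE fit leaves the pairing by lysate out. With the lysate as a block, an alternative, the TE calls were 3025, 4274, 4145, 5240 and 6835 without arginine, BCAA, glucose, glutamine and methionine, where the fit gave 2162, 3518, 3370, 4602 and 6416. They were 0, 330 and 630 with halofuginone, Torin1 and 4EGI-1, where it gave 0, 228 and 72.

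Gene lists were written before the data were examined, as were the rule for named genes, all alternatives except 1 and the tests of each condition against its control, of polysome over total RNA, of shared responses within an experiment and between deprivations. The tests between drugs and across the experiments, and those that the closing section names as such, were chosen later. The lists covered targets of ATF4 in the integrated stress response (ISR), aminoacyl-tRNA synthetases, mRNAs with upstream open reading frames (uORF) reported to resist eIF2α phosphorylation, ribosomal proteins, other mRNAs with a 5′ terminal oligopyrimidine motif (TOP), ribosome biogenesis, SREBP2 targets of cholesterol synthesis, glycolysis and HIF targets, the endoplasmic reticulum stress response, CD8 effector genes, naive and memory T cell genes, effector transcription factors, cell cycle, nuclear-encoded and mitochondrially encoded oxidative phosphorylation, lysosome and autophagy, p53 targets, NRF2 targets, heat shock, polyamines, 1-carbon and methyl metabolism, MondoA targets, immediate early genes, interferon response, snoRNA host genes, nuclear long non-coding RNAs and replication histones. Others marked CD8 T, CD4 T, B, myeloid, NK and erythroid cells. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Members were counted as changed when adjusted over all genes and also adjusted over the list alone.

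The text names genes among, per condition, the 4 highest and 4 lowest called genes in total RNA and in TE, the 3 and 3 in polysome RNA, and the 6 and 6 in polysome over total RNA of untreated cells. All had a mean log2 CPM of at least 2, and in total and polysome RNA all 3 libraries of the condition lay on the same side of all 3 control libraries. Predicted genes (Gm, Rik, pseudogenes, no symbol) were left out of these ranks. The text also names 11 genes chosen in advance and up to 4 members of each described list, in order of adjusted p. Other genes are said to have been chosen after their values were seen.

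Differences between conditions were tested as direct contrasts. Overlaps of calls were set beside the number expected for independent lists, and correlations of fold changes across genes beside values simulated for unchanged groups that share their controls. Alternatives were RLE size factors, no filter on low counts, DESeq2 1.42.0 (Wald test), a replicate or lysate block, a fit of only the groups compared, and leaving out each library. Leaving out 5 entries derived from ribosomal RNA was added after the data were seen. Each comparison was also run on the 10 splits of its 6 libraries (6 lysates for TE), with seed 1. On simulated data with known changes, 2-fold changes were recovered for 85.1% of genes in total RNA without arginine, 91% in polysome RNA and 74.6% in TE. With halofuginone the shares were 85.1%, 71.6% and 61.2%. Depth limits precision further for genes of low count, and 60 replicate pairs differed by 3.49 to 71.19 times the variance of counting alone.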

Results

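The data were read counts from mouse CD8+ T cells on day 3 of activation. In the nutrient experiment the cells spent 3 h in complete medium (Control) or in medium without arginine, branched-chain amino acids (BCAA), glucose, glutamine or methionine. In the drug experiment they spent 3 h with the solvent DMSO or with halofuginone, an inhibitor of prolyl-tRNA synthetase, Torin1, an inhibitor of the kinase mTOR, or 4EGI-1, a compound that blocks the binding of eIF4E to eIF4G. Total RNA and polysome RNA, from the gradient fractions in which several ribosomes sit on an mRNA, were sequenced from each lysate. That gave 12 nutrient groups and 8 drug groups of 3 libraries each, 60 libraries in all. Total counts per library ran from 15144663 to 30637485 (nutrient, total RNA), 29917770 to 54272886 (nutrient, polysome), 17506526 to 23099949 (drug, total RNA) and 17846266 to 24929556 (drug, polysome).

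Changes are log2 fold changes against Control or DMSO, with ± for the standard error of the fit. Levels are means ± SD of counts scaled to the library total times the TMM factor (CPM). Summed histone levels, ranges of markers and shares of counts use the plain library total instead. All are from 3 libraries per group. Genes are called by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05, and genes named for their rank in total or polysome RNA had all 3 libraries of the condition on the same side of all 3 control libraries. P-values measure only the spread between these libraries, since nothing says whether they came from separate cultures or animals. Gene lists had been fixed in advance, some share members, and their tests used a preset correlation between genes. Of 275 list calls, 52 held with an estimated correlation, whose adjusted p is printed beside each list. Replication histones, ribosomal proteins and entries such as Rn18s-rs5 share sequence with paralogs or ribosomal RNA, so their values are less certain than those of other genes.

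Which RNAs sat on polysomes before any stress was asked by comparing polysome with total RNA in untreated cells. In Control, several non-coding RNAs were depleted from polysomes, though no list covered non-coding RNAs as a class. The 7SK RNA Rn7sk fell by 7.13 ± 0.25 (adjusted p = 1.4e-21), from 11078 ± 1093 CPM in total RNA to 79.2 ± 9.24 CPM, and the small cytoplasmic RNA Bc1 fell by 6.78 ± 0.30. Both measured nuclear long non-coding RNAs were lower, Rn7sk and Neat1 (-1.73 ± 0.14) (2 of 2 adjusted over the list alone; adjusted p = 0.00081 with an estimated correlation). All 12 snoRNA host genes were lower (12 adjusted over the list alone; adjusted p = 0.0048 with an estimated correlation), with a median of -2.08 and Snhg8 at -3.06 ± 0.13. All 10 mitochondrially encoded mRNAs were lower too, with a median of -2.96 (10 adjusted over the list alone; adjusted p = 0.0085 with an estimated correlation), among them mt-Nd1 at -4.25 ± 0.20 and mt-Co2 at -4.76 ± 0.26. Other low RNAs were Mir142hg (-4.28 ± 0.14) and the mitochondrial ribosomal RNA mt-Rnr2 (-3.55 ± 0.33).

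Ribosomal protein mRNAs and other TOP mRNAs in Control also had low ratios. Of 78 ribosomal protein mRNAs 77 were lower in polysome than in total RNA, with a median of -0.89 (77 adjusted over the list alone; adjusted p = 0.16 with an estimated correlation), for example Rps12 at -2.90 ± 0.11 and Rps27 at -2.27 ± 0.09. Of 19 other TOP mRNAs 16 were lower and 1 higher (16 and 1 adjusted over the list alone; adjusted p = 0.00051 with an estimated correlation), including the elongation factor Eef1a1 at -1.49 ± 0.06 and Tpt1 at -2.08 ± 0.10. The highest ratios were those of the histone methyltransferase genes Kmt2d (1.69 ± 0.29), Setd1b (1.58 ± 0.25) and Kmt2a (1.47 ± 0.17), of Hivep3 (1.56 ± 0.24), of the nucleoporin gene Pom121 (1.43 ± 0.16) and of the transcription factor gene Sp2 (1.38 ± 0.18). Of 18 CD8 effector genes 13 were higher and 2 lower (13 and 2 adjusted over the list alone), and the list as a whole was not called (adjusted p = 0.088, and adjusted p = 0.9 with an estimated correlation). Granzyme B (Gzmb) stood at 0.60 ± 0.10, interferon gamma (Ifng) at 0.48 ± 0.10 and Cd8a at 0.48 ± 0.10. Of 13072 genes 4919 were higher in polysomes and 3664 lower. The share that was higher, 57.31%, depended on the scaling: it was 50.2% with RLE size factors and 44.8% without the entries derived from ribosomal RNA, which moved the median of all genes by -0.142.

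In DMSO-treated cells the ranking was led by other genes. Replication histone mRNAs were enriched on polysomes in 17 of 18 cases, with a median of 1.56 (17 adjusted over the list alone; adjusted p = 0.42 with an estimated correlation). The labels call the drug libraries polyA RNA, and replication histone mRNAs mostly lack a poly(A) tail. Together the 18 genes had 64.26 ± 5.21 CPM in DMSO total RNA and 2342 ± 54.7 in Control, so the DMSO ratios cover only the histone RNA that these libraries took up. H3c3 stood at 2.29 ± 0.16 (67.5 ± 9.88 CPM against 13.8 ± 1.53), H2ac8 at 2.21 ± 0.31, H3c7 at 2.16 ± 0.29 and H3c1 at 2.15 ± 0.27. The immunophilin gene Fkbp11 (2.20 ± 0.23) and the proteasome subunit gene Psmb5 (2.13 ± 0.15) were also among the highest. Of 38 nuclear genes of oxidative phosphorylation 30 were enriched and 0 depleted (30 and 0 adjusted over the list alone; adjusted p = 0.42 with an estimated correlation), led by Ndufa9 at 1.40 ± 0.11. Ifng was enriched by 1.33 ± 0.14. The lowest ratios were those of Bc1 (-4.28 ± 0.52), mt-Rnr2 (-3.53 ± 0.49), mt-Rnr1 (-3.42 ± 0.37), the potassium channel gene Kcna3 (-3.38 ± 0.39), Tmem123 (-2.93 ± 0.16) and the non-coding Dleu2 (-2.92 ± 0.36). Ribosomal protein mRNAs had a median of 0.34, 42 of 77 higher and 9 lower (42 and 9 adjusted over the list alone; adjusted p = 0.81 with an estimated correlation), and without DMSO replicate 3 the list was not called (25 higher, adjusted p = 0.14). Of 12745 genes 3616 were higher and 3938 lower. Whether Control and DMSO differed was not tested, because they come from separate experiments.

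Removing arginine for 3 h asked how cells respond to the loss of an amino acid that T cells take up. The clearest response in total RNA was a stress program. Ddit3, which encodes the transcription factor CHOP, rose by 1.24 ± 0.07 (adjusted p = 1.5e-09), from 17.9 ± 0.462 to 42.2 ± 1.75 CPM. Chac1, whose product degrades glutathione, rose by 1.46 ± 0.10 and the pseudokinase gene Trib3 by 1.11 ± 0.07. Of 27 measured targets of ATF4 in the integrated stress response (ISR) 18 rose and 0 fell, with a median of 0.35 (20 adjusted over the list alone; adjusted p = 3.4e-05 with an estimated correlation). Of 6 targets of the sugar-sensing factor MondoA 3 rose, Hbp1 by 0.78 ± 0.10, Txnip by 0.59 ± 0.09 and Klf10 by 0.50 ± 0.10 (3 adjusted over the list alone; adjusted p = 0.016 with an estimated correlation). All 18 replication histones rose, with a median of 1.07 (18 adjusted over the list alone; adjusted p = 0.018 with an estimated correlation), led by H2ac15 (1.83 ± 0.30) and H2ac8 (1.78 ± 0.39). Immediate early genes rose in 8 of 18 cases and fell in 1 (8 and 1 adjusted over the list alone; adjusted p = 0.052 with an estimated correlation), with Egr2 at 1.05 ± 0.08. Effector chemokines were among 5 of 18 CD8 effector genes that rose (5 adjusted over the list alone; adjusted p = 0.34 with an estimated correlation), Ccl5 by 0.95 ± 0.13, Ccl3 by 0.56 ± 0.08 and Xcl1 by 0.66 ± 0.11.

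Lower without arginine were Syde2, a GTPase regulator gene (-1.09 ± 0.15), Kctd11 (-0.84 ± 0.09), the chaperone gene Dnajb4 (-0.82 ± 0.10) and the stress response gene Ier3 (-0.81 ± 0.08). Cholesterol synthesis genes fell in 8 of 23 cases (9 adjusted over the list alone; adjusted p = 0.016 with an estimated correlation), Hmgcs1 by 0.64 ± 0.08 and Acat2 by 0.53 ± 0.06. Glycolysis and HIF targets fell in 8 of 20 cases (13 adjusted over the list alone; adjusted p = 0.016 with an estimated correlation), among them Pgam1 (-0.29 ± 0.05) and the glucose transporter gene Slc2a3 (-0.35 ± 0.07). In all, 645 genes rose and 523 fell of 12642. The total of 1168 was 617 without Control replicate 1, 710 without Control replicate 3, 637 without arginine-free replicate 1 and 646 without arginine-free replicate 2. The entries Mir6236 (2.38 ± 0.52) and Rn18s-rs5 (2.33 ± 0.46), which share sequence with ribosomal RNA, had the highest values of all. Both were high in arginine-free replicate 2, where mitochondrial ribosomal RNA also took 4.98% of counts against 1.74% and 1.56% in the other libraries of the group, and Mir6236 was not called without that library (1.29, adjusted p = 0.088).

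Removing the BCAA asked the same of the branched-chain amino acids. Ddit3 rose by 3.27 ± 0.07 (adjusted p = 6.4e-18), from 17.9 ± 0.462 to 172 ± 12.0 CPM, Nupr1, a stress-induced chromatin protein gene, by 3.06 ± 0.12 and Trib3 by 2.86 ± 0.08. Of 27 ISR targets 26 rose and 0 fell, with a median of 1.09 (26 adjusted over the list alone; adjusted p = 1.5e-07 with an estimated correlation), including Atf3 (2.11 ± 0.06) and the phosphatase subunit gene Ppp1r15a (2.09 ± 0.07). Of 11 uORF mRNAs 9 rose and 2 fell (9 and 2 adjusted over the list alone; adjusted p = 1.9e-06 with an estimated correlation), and Atf5 rose by 1.55 ± 0.11. Aminoacyl-tRNA synthetase genes rose in 13 of 19 cases (13 adjusted over the list alone; adjusted p = 0.096 with an estimated correlation), for example Aars1 by 1.06 ± 0.08 and Cars1 by 0.99 ± 0.06. All 18 histones rose, with a median of 1.36 (18 adjusted over the list alone; adjusted p = 0.09 with an estimated correlation), and H2ac8 stood at 2.78 ± 0.37. Cholesterol synthesis genes fell in 20 of 23 cases (21 adjusted over the list alone; adjusted p = 1.6e-05 with an estimated correlation). Hmgcs1, the HMG-CoA synthase gene, fell by 1.86 ± 0.08, from 629.6 ± 60.3 to 174 ± 9.16 CPM, and Acat2 by 1.36 ± 0.06. Cell cycle genes fell in 11 of 24 cases and rose in 2 (11 and 2 adjusted over the list alone; adjusted p = 0.22 with an estimated correlation), with Ccne2, cyclin E2, at -1.32 ± 0.09. The other lowest genes were Syde2 (-1.89 ± 0.16), Fnip2 (-1.67 ± 0.17) and the tubulin gene Tubb6 (-1.57 ± 0.09). In all, 2075 genes rose and 1725 fell.

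Removing glucose asked how cells respond to the loss of their main sugar. Ddit3 rose by 2.89 ± 0.07 (adjusted p = 6.5e-17), to 133 ± 1.55 CPM, Trib3 by 2.69 ± 0.08, Nupr1 by 2.40 ± 0.12, the AP-1 repressor gene Jdp2 by 2.40 ± 0.16 and Chac1 by 2.10 ± 0.10. Of 27 ISR targets 26 rose and 0 fell, with a median of 0.74 (26 adjusted over the list alone; adjusted p = 2.2e-05 with an estimated correlation), and of 11 uORF mRNAs 7 rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 6.2e-05 with an estimated correlation). Aminoacyl-tRNA synthetase genes rose in 15 of 19 cases (15 adjusted over the list alone; adjusted p = 0.32 with an estimated correlation). Txnip, the MondoA target that restrains glucose uptake, fell by 1.29 ± 0.10, from 62.8 ± 8.02 to 25.8 ± 2.64 CPM. Dgcr8, a Microprocessor subunit gene, fell by 1.93 ± 0.11, Mat2a, whose product makes S-adenosylmethionine, by 1.77 ± 0.08, Ccne2 by 1.66 ± 0.10 and the amine oxidase gene Aoc2 by 2.36 ± 0.27. Effector genes fell in 9 of 18 cases and rose in 2 (9 and 2 adjusted over the list alone; adjusted p = 0.52 with an estimated correlation): Ifng by 0.70 ± 0.08, from 1412 ± 102 to 868 ± 39.7 CPM, lymphotoxin (Lta) by 0.98 ± 0.09 and perforin (Prf1) by 0.86 ± 0.09, while the chemokine gene Xcl1 rose by 0.89 ± 0.11. Gzmb fell by 0.51 ± 0.09. Cholesterol synthesis genes fell in 16 of 23 cases (17 adjusted over the list alone; adjusted p = 0.00023 with an estimated correlation), with Fdps at -1.58 ± 0.13. In all, 2751 genes rose and 2408 fell.

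Removing glutamine asked the same of the amino acid that feeds the tricarboxylic acid cycle. Ddit3 rose by 3.55 ± 0.07 (adjusted p = 1.4e-18), to 209 ± 4.92 CPM, Nupr1 by 3.55 ± 0.12 and Trib3 by 3.06 ± 0.08. Of 27 ISR targets 26 rose and 0 fell, with a median of 0.98 (26 adjusted over the list alone; adjusted p = 1e-06 with an estimated correlation), among them Sesn2, which encodes an inhibitor of mTORC1, by 2.38 ± 0.08. Glycolysis and HIF targets fell in 16 of 20 cases, with a median of -0.56 (17 adjusted over the list alone; adjusted p = 0.00044 with an estimated correlation). The glucose transporter gene Slc2a1 fell by 1.80 ± 0.09, from 421 ± 34.4 to 121 ± 7.30 CPM, the lactate transporter gene Slc16a3 by 1.60 ± 0.11 and the HIF prolyl hydroxylase gene Egln3 by 1.29 ± 0.06. Ak4, a mitochondrial adenylate kinase gene, fell by 3.01 ± 0.08, from 90.4 ± 3.80 to 11.3 ± 0.338 CPM. Also among the lowest were the Wnt receptor gene Fzd7 (-2.43 ± 0.12), Ier3 (-2.34 ± 0.09) and Syde2 (-2.27 ± 0.16). Effector genes fell in 10 of 18 cases and rose in 1 (10 and 1 adjusted over the list alone; adjusted p = 0.52 with an estimated correlation), Prf1 by 1.45 ± 0.09, the interleukin-2 receptor gene Il2ra by 0.93 ± 0.09 and Ifng by 0.76 ± 0.08. Txnip rose by 1.64 ± 0.09. Cholesterol synthesis genes fell in 21 of 23 cases (21 adjusted over the list alone; adjusted p = 6.3e-05 with an estimated correlation). All 18 histones rose, with a median of 1.47 (18 adjusted over the list alone; adjusted p = 0.081 with an estimated correlation), H2ac8 by 2.95 ± 0.37. In all, 2575 genes rose and 2354 fell.

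Removing methionine asked the same of the amino acid that starts proteins and supplies methyl groups. Ddit3 rose by 3.02 ± 0.07 (adjusted p = 2.8e-17), to 146 ± 12.3 CPM, and Nupr1 by 2.87 ± 0.12. Immediate early genes rose in 15 of 18 cases and fell in 1, with a median of 1.06 (16 and 1 adjusted over the list alone; adjusted p = 0.001 with an estimated correlation): Fos by 2.92 ± 0.11, Egr2 by 2.87 ± 0.08, from 13.6 ± 0.878 to 99.7 ± 6.78 CPM, and Nr4a1 by 2.16 ± 0.08. Myc rose by 0.46 ± 0.10. Of 27 ISR targets 26 rose and 0 fell, with a median of 0.90 (27 adjusted over the list alone; adjusted p = 2.3e-06 with an estimated correlation). Of 6 MondoA targets 4 rose, Txnip by 1.31 ± 0.09 (4 adjusted over the list alone; adjusted p = 0.03 with an estimated correlation). Cholesterol synthesis genes fell in 21 of 23 cases (21 adjusted over the list alone; adjusted p = 8.2e-06 with an estimated correlation), Hmgcs1 by 1.87 ± 0.08 and Acat2 by 1.86 ± 0.06. Glycolysis and HIF targets fell in 16 of 20 cases (16 adjusted over the list alone; adjusted p = 0.0027 with an estimated correlation), with the phosphofructokinase gene Pfkl at -0.82 ± 0.08. Kctd11 (-1.99 ± 0.10) and the phosphatase gene Pdxp (-1.78 ± 0.13) were also among the lowest. Mat2a rose by 1.01 ± 0.08, from 325 ± 31.1 to 656 ± 25.0 CPM. In all, 2468 genes rose and 1980 fell.

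**Figure D1:**
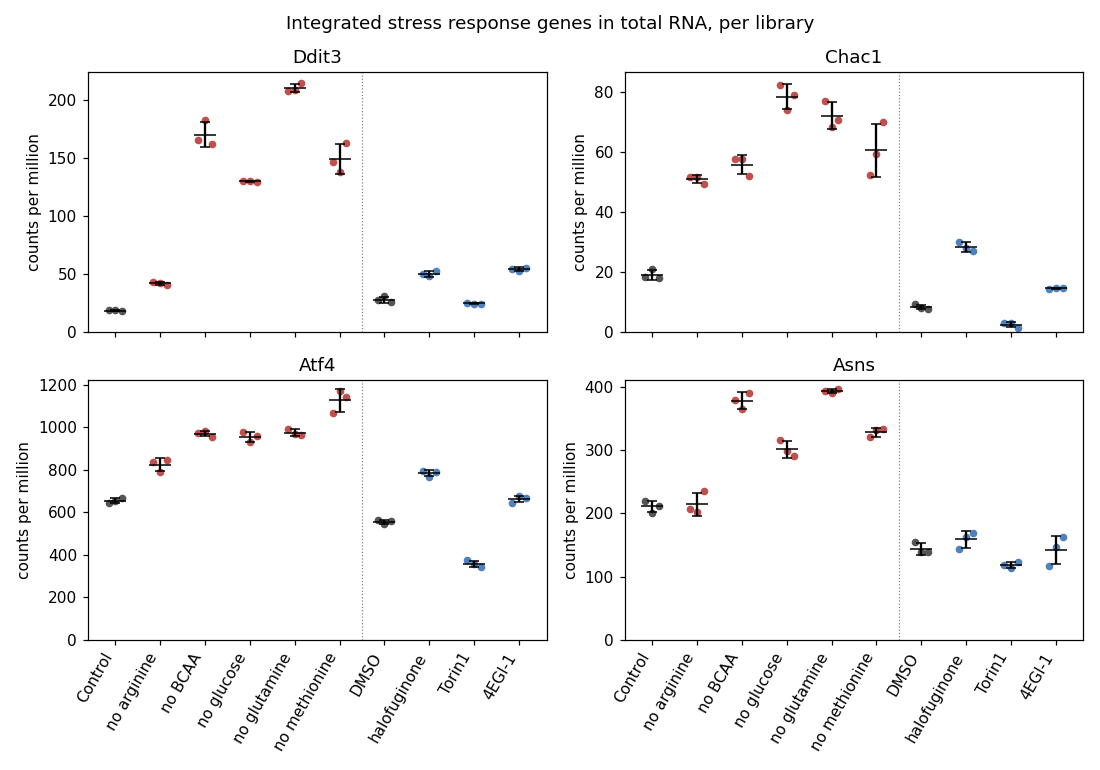
CPM, by the plain library total, of Ddit3, Chac1, Atf4 and Asns in each total RNA library of the 10 groups, with the group mean and SD. Ddit3 was at 18.14 ± 0.56 CPM in Control and at 210.4 ± 3.69 without glutamine. With Torin1, Chac1 was at 2.313 ± 0.836 CPM against 8.219 ± 0.796 in DMSO.

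Whether the deprivations differed from one another was tested directly. ISR targets were lower without arginine than without BCAA (25 of 27 members lower; adjusted p = 9.5e-07 with an estimated correlation), glucose (21 lower; 0.0017), glutamine (26 lower; 1.5e-05) or methionine (24 lower; 1.7e-05). They were also lower without glucose than without glutamine (20 lower and 1 higher; adjusted p = 0.0039 with an estimated correlation). Asns, asparagine synthetase, stood at 0.06 ± 0.06 without arginine (adjusted p = 0.61), and rose by 0.88 ± 0.06 without BCAA, 0.57 ± 0.06 without glucose, 0.91 ± 0.06 without glutamine and 0.62 ± 0.06 without methionine. Atf4 rose by 0.37 ± 0.06, 0.61 ± 0.06, 0.60 ± 0.06, 0.58 ± 0.06 and 0.77 ± 0.06 without arginine, BCAA, glucose, glutamine and methionine, and the polyamine enzyme gene Odc1 fell by 0.27 ± 0.05, 0.39 ± 0.05, 0.26 ± 0.05, 0.48 ± 0.05 and 0.33 ± 0.05. MondoA targets were lower without glucose than under each of the other 4 deprivations (adjusted p from 0.0061 to 0.034 with an estimated correlation), and Txnip was 2.92 ± 0.10 lower without glucose than without glutamine (log2 difference -2.92). Ifng was higher without arginine than without glucose by 0.77 ± 0.08 and higher without BCAA than without glucose by 0.80 ± 0.08, while without glucose and without glutamine it differed by 0.06 ± 0.08 (adjusted p = 0.62). Glycolysis genes were lower without glutamine than without glucose (16 of 20 lower; adjusted p = 0.0027 with an estimated correlation). Cholesterol synthesis genes were higher without arginine than under the other 4 (16 to 19 of 23 members higher; adjusted p from 1.7e-05 to 0.0017 with an estimated correlation). Immediate early genes were higher without methionine than without arginine, BCAA or glucose (13, 14 and 14 of 18 higher; adjusted p = 0.002, 0.013 and 0.0061 with an estimated correlation).

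A core of genes moved under every deprivation. In total RNA 329 genes rose and 185 fell in all 5, where independent lists would share 0.916 and 0.396 genes. The highest mean changes were those of Ddit3 (2.79, range 1.24 to 3.55), Nupr1 (2.66, range 1.41 to 3.55) and Trib3 (2.45). Fold changes of pairs of deprivations correlated across genes at 0.397 to 0.779, and unchanged groups that share their controls gave 0.454 to 0.475 in simulation. The simulated groups hold no real effects, so these correlations cannot be set against one another directly. Covariances of the fold changes lay above the simulated ones by 0.0367 to 0.144. Genes are not independent replicates, and all 5 comparisons use the same 3 Control libraries.

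Polysome RNA asked which mRNAs the ribosomes engaged after each deprivation. Ddit3 mRNA rose on polysomes by 1.52 ± 0.08 without arginine (adjusted p = 3.7e-10), 3.81 ± 0.09 without BCAA, 3.29 ± 0.09 without glucose, 3.91 ± 0.09 without glutamine and 3.06 ± 0.09 without methionine. Nupr1 rose by 1.56 ± 0.09, 3.17 ± 0.09, 2.49 ± 0.09, 3.73 ± 0.09 and 2.15 ± 0.09 in the same order, and Slc1a4, a neutral amino acid transporter gene, by 1.67 ± 0.13 without arginine, 2.77 ± 0.13 without BCAA and 3.42 ± 0.14 without methionine, where it reached 310.2 ± 38.4 CPM from 28.9 ± 1.51. ISR targets rose in 22, 26, 26, 25 and 25 of 27 cases and fell in 1, 0, 0, 0 and 0 (adjusted over the list alone 23, 26, 26, 26 and 25 rose; adjusted p from 3.2e-06 to 0.00059 with an estimated correlation). Aminoacyl-tRNA synthetases rose in 14, 17, 16, 16 and 18 of 19 cases (15, 17, 16, 17 and 18 adjusted over the list alone; adjusted p from 0.21 to 0.41 with an estimated correlation), and Eprs1 rose by 0.69 ± 0.10, 1.39 ± 0.10, 1.80 ± 0.10, 1.64 ± 0.10 and 1.73 ± 0.10.

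The highest and lowest polysome changes of each medium were as follows. Without glucose they included Trib3 (2.66 ± 0.08), the guanine exchange factor gene Rasgef1b (2.65 ± 0.12), Dgcr8 (-1.99 ± 0.10), Ccne2 (-1.75 ± 0.09) and Aoc2 (-2.14 ± 0.19). Without glutamine they included Tsc22d3, the glucocorticoid-induced leucine zipper gene (3.08 ± 0.06), Ak4 (-3.40 ± 0.10), Tlcd3a (-2.81 ± 0.15) and the lipid droplet gene Hilpda (-2.63 ± 0.08). Without methionine they included Egr2 (3.71 ± 0.08), the uracil glycosylase gene Ung (-2.24 ± 0.11), Pdxp (-2.14 ± 0.11) and Kctd11 (-2.06 ± 0.11), without BCAA the Polycomb gene Cbx2 (-2.24 ± 0.13), Tubb6 (-2.02 ± 0.08) and Eeig1 (-1.80 ± 0.10), and without arginine Cacybp (-1.05 ± 0.09), Rtraf (-0.96 ± 0.09) and Ier3 (-0.89 ± 0.10). Gzmb fell on polysomes by 0.33 ± 0.10 without BCAA, 0.72 ± 0.10 without glucose, 0.66 ± 0.10 without glutamine and 0.57 ± 0.10 without methionine, and stood at 0.08 ± 0.10 without arginine (adjusted p = 0.51). The numbers of genes that rose and fell were 2355 and 2679 without arginine, 3558 and 3402 without BCAA, 3678 and 3651 without glucose, 3996 and 4018 without glutamine and 4254 and 4312 without methionine. The split depended on the scaling. With RLE size factors it was 2748 and 2286 without arginine, where the share up went from 46.78% to 54.59%, and the share up went from 49.86% to 50.42% without glutamine and from 49.66% to 50.18% without methionine. Of the genes called, 1421 rose and 1430 fell in all 5, where independent lists would share 22 and 24.3.

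**Figure D2:**
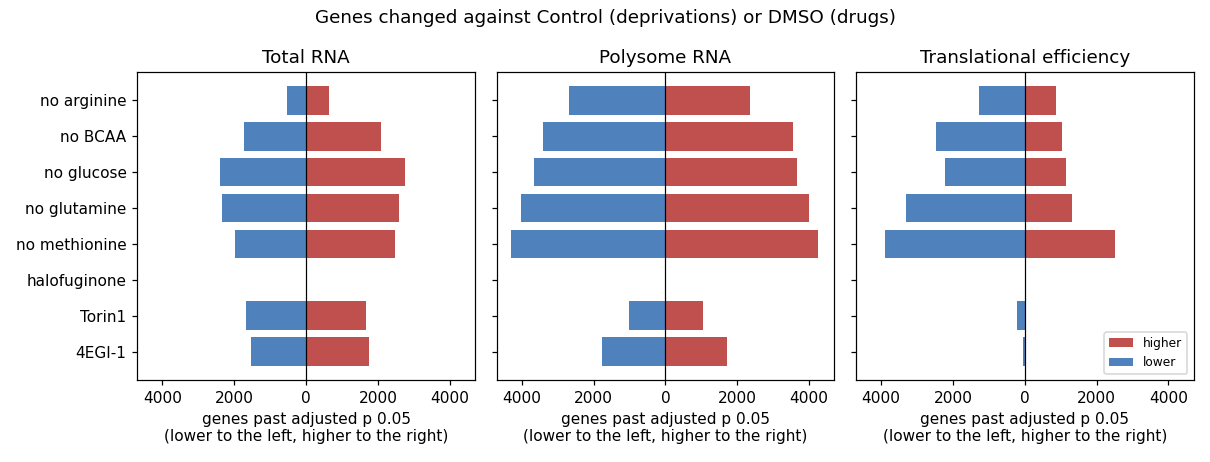
Number of genes that rose (right) and fell (left) in total RNA, polysome RNA and translational efficiency for each deprivation and drug. Without methionine 4254 genes rose on polysomes and 2468 in total RNA; with halofuginone 5 and 30 did.

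Translational efficiency (TE), the change in polysome RNA beyond that in total RNA, asked which mRNAs gained or lost ribosomes. Of 78 mRNAs of ribosomal proteins, 29 to 72 fell in each deprivation, and the list call held with an estimated correlation only without glucose. Without arginine 70 of 78 fell (73 adjusted over the list alone; adjusted p = 0.12 with an estimated correlation), without BCAA 29 fell and 1 rose (31 and 1; 0.69), without glucose 72 fell (72; 0.039), without glutamine 58 fell (59; 0.73), and without methionine 61 fell and 2 rose (66 and 3; 0.61). The medians were -0.61, -0.28, -0.93, -0.48 and -0.62. Without glucose Rpl32 fell by 1.54 ± 0.16 (adjusted p = 2.8e-08), Rpl39 by 1.40 ± 0.18, Rpl7a by 1.02 ± 0.09 and Rpl35rt, a retrogene copy that can take reads of its parent, by 1.61 ± 0.22. Relative to the median of all genes the list stood at -0.572, -0.154, -0.853, -0.335 and -0.486. Ribosomal proteins were higher without BCAA than without glucose (54 of 78 members, 66 adjusted over the list alone; adjusted p = 0.0093 with an estimated correlation).

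Other TOP mRNAs moved apart between the media. Without glucose 12 of 19 fell and 0 rose (14 and 0 adjusted over the list alone; adjusted p = 0.0011 with an estimated correlation), the nucleolar protein gene Npm1 by 1.18 ± 0.10 (adjusted p = 5.5e-10) and the elongation factor gene Eef1b2 by 1.07 ± 0.11. Without methionine 11 rose and 4 fell (13 and 4 adjusted over the list alone; adjusted p = 0.036 with an estimated correlation), the elongation factor genes Eef1a1 by 1.00 ± 0.08 and Eef2 by 0.94 ± 0.10. The list was lower without glucose than without BCAA, glutamine or methionine (13, 13 and 18 of 19 members; adjusted p = 2.5e-10, 1.5e-08 and 1.9e-08 with an estimated correlation). Nuclear mRNAs of oxidative phosphorylation fell in 20, 23, 25, 28 and 27 of 38 cases without arginine, BCAA, glucose, glutamine and methionine and rose in 3, 2, 2, 2 and 5 (24, 27, 27, 28 and 28 fell adjusted over the list alone; adjusted p from 0.53 to 0.73 with an estimated correlation). Without methionine the cytochrome c gene Cycs fell by 1.55 ± 0.13 and Ndufa4 by 1.54 ± 0.14.

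Aminoacyl-tRNA synthetase mRNAs rose in TE in 13, 10, 8, 10 and 17 of 19 cases in the same order, and 1 fell without glucose (14, 10, 9, 10 and 18 rose adjusted over the list alone; adjusted p from 0.22 to 0.57 with an estimated correlation). Eprs1 rose by 0.78 ± 0.14, 0.81 ± 0.14, 1.06 ± 0.14, 0.93 ± 0.14 and 1.27 ± 0.14, the last with an adjusted p of 8.1e-09, and Rars1 by 0.71 ± 0.11 to 0.96 ± 0.11. Ribosome biogenesis mRNAs rose in 7, 7, 5, 5 and 15 of 25 cases and fell in 0, 1, 1, 3 and 3 (7, 7, 5, 8 and 15 rose adjusted over the list alone; adjusted p from 0.53 to 0.73 with an estimated correlation), with Polr1b, an RNA polymerase I subunit gene, up by 0.61 ± 0.13 to 0.85 ± 0.13. Of 11 uORF mRNAs 5 rose without glucose (6 adjusted over the list alone; adjusted p = 0.0099 with an estimated correlation), Atf4 by 0.57 ± 0.09 (adjusted p = 2.5e-05). Atf4 also rose without BCAA by 0.43 ± 0.09, and stood at 0.23 ± 0.09 without arginine, 0.12 ± 0.09 without glutamine and 0.06 ± 0.09 without methionine (adjusted p = 0.078, 0.35 and 0.65). Zfp953 mRNA had the highest mean gain over the 5 media, 1.00 (range 0.86 to 1.13), followed by Eprs1 at 0.97 and the transferrin receptor gene Tfrc at 0.95.

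The genes with the largest TE changes in each medium follow. Without arginine they included Slc7a3, a cationic amino acid transporter gene (0.90 ± 0.17), Zfp953 (0.86 ± 0.19), Wdr19 (0.81 ± 0.21) and the receptor kinase gene Kit (0.80 ± 0.19), and at the other end Arhgef26 (-1.87 ± 0.41). Wdr19 was not called without arginine-free replicate 1 or 2 (adjusted p = 0.065 and 0.0504), and Kit not without Control replicate 2 (0.052). The lowest values, of Rn18s-rs5 (-3.92 ± 0.89), Mir6236 (-2.94 ± 0.78) and Lars2 (-2.74 ± 0.73), whose counts include ribosomal RNA, were not called without arginine-free replicate 2 (adjusted p = 0.056, 0.1 and 0.4), and that of Mir6236 also not without Control replicate 1 (0.069) and that of Lars2 not when only the groups compared were fitted (0.055). Without BCAA they included Zfp60 (1.00 ± 0.16), Wdr7 (0.95 ± 0.14) and Wdr35 (0.95 ± 0.17) at the top. Bckdk, the kinase that restrains BCAA breakdown, fell by 1.22 ± 0.12 (adjusted p = 6.2e-08), Lrrfip2 by 1.22 ± 0.13, Chchd7 by 1.20 ± 0.18 and Arhgef26 by 1.46 ± 0.41, the last not called without Control replicate 1 (-0.96, adjusted p = 0.099). Without glucose the kinase gene Rps6ka5 (1.10 ± 0.20), Zik1 (1.09 ± 0.19) and Zfp953 (1.07 ± 0.18) rose most and Arhgef26 fell by 1.72 ± 0.41. Without glutamine Zfp953 (1.13 ± 0.19), the chromatin ATPase gene Atad2 (1.08 ± 0.14), Plcg2 (1.03 ± 0.17) and topoisomerase Top2a (1.01 ± 0.14) rose most, while Bckdk (-1.33 ± 0.12), Smim8 (-1.29 ± 0.21), Mark4 (-1.22 ± 0.18) and Chchd7 (-1.21 ± 0.18) fell most.

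Without methionine CD8 effector mRNAs fell in TE in 12 of 18 cases and rose in 1 (12 and 1 adjusted over the list alone; adjusted p = 0.68 with an estimated correlation), the chemokine genes Ccl3 by 1.46 ± 0.13 (adjusted p = 3e-10), Ccl4 by 1.35 ± 0.14 and Xcl1 by 1.29 ± 0.17. Ifng fell by 0.65 ± 0.14. All 18 replication histones fell, with a median of -1.66 (18 adjusted over the list alone; adjusted p = 0.61 with an estimated correlation), with H1f1 at -1.26 ± 0.11 and H2ac11 at -2.57 ± 0.66. H2ac13 (-2.30 ± 0.74) and H2ac22 (-2.15 ± 0.71) were not called without Control replicate 3 (adjusted p = 0.059 and 0.068) or methionine-free replicate 2 (0.11 and 0.14), nor was Rn18s-rs5 (-2.65 ± 0.87) without Control replicate 1 (0.12) or methionine-free replicate 1 (0.093). The highest gains were those of Tfrc (1.32 ± 0.15), Trim21 (1.30 ± 0.20), Os9, which sorts misfolded glycoproteins (1.29 ± 0.18), and Eprs1.

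The number of TE calls was large in each medium, and its split depended on the scaling. Genes up and down were 879 and 1283 without arginine, 1050 and 2468 without BCAA, 1156 and 2214 without glucose, 1305 and 3297 without glutamine and 2512 and 3904 without methionine. The share up was 40.66%, 29.85%, 34.3%, 28.36% and 39.15%, and 42.62%, 42.96%, 51.03%, 49.46% and 46.32% with RLE size factors. Without the entries derived from ribosomal RNA it was 60.89%, 60.37%, 59.91%, 54.42% and 50.52%. RLE moved the median of all genes by 0.131 without glutamine, and leaving out those entries by 0.136, 0.125, 0.161 and 0.123 without BCAA, glucose, glutamine and methionine. The 2162 calls without arginine became 1185 without Control replicate 2, 1371 without Control replicate 3, 526 without arginine-free replicate 1, 983 without arginine-free replicate 2 and 1326 when only the groups compared were fitted, and the 3370 without glucose became 2168 without glucose-free replicate 1. In all 5 media 508 genes rose and 654 fell, where independent lists would share 0.12 and 3.09.

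**Figure D3:**
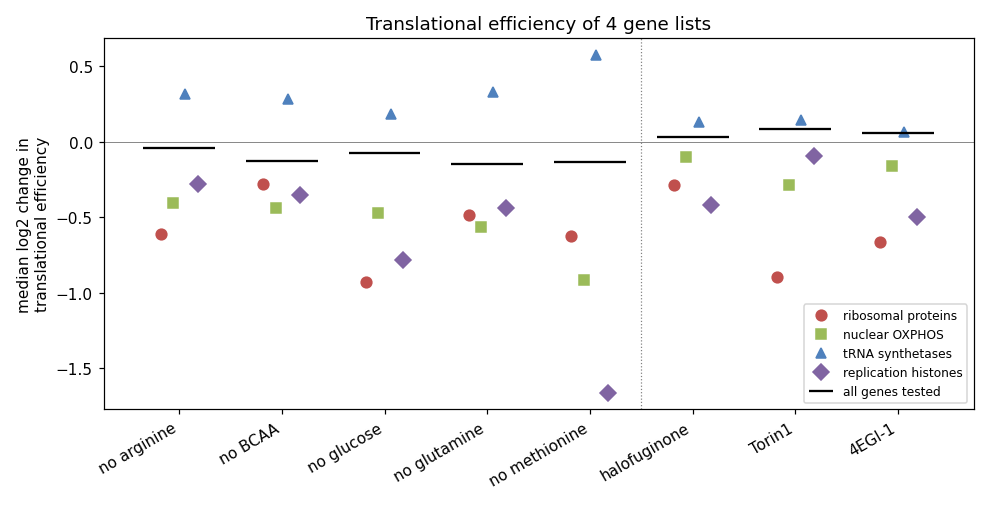
Median log2 change in translational efficiency of ribosomal protein, nuclear oxidative phosphorylation, aminoacyl-tRNA synthetase and replication histone mRNAs and of all genes, for each deprivation and drug. Ribosomal proteins were at -0.93 without glucose and -0.89 with Torin1, where the medians of all genes were -0.0751 and 0.0824.

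Halofuginone asked what a block of prolyl-tRNA charging does in cells with all nutrients. A small set of stress genes rose in total RNA. Chac1 rose by 1.77 ± 0.14 (adjusted p = 4.5e-06), from 8.25 ± 0.662 to 28.2 ± 1.25 CPM, Sesn2 by 0.97 ± 0.09, Slc1a4 by 0.96 ± 0.10, Trib3 by 0.95 ± 0.15, Ddit3 by 0.85 ± 0.08 and Atf4 by 0.49 ± 0.06. Of 27 ISR targets 9 rose and 0 fell (17 adjusted over the list alone; adjusted p = 0.00012 with an estimated correlation), and of 11 uORF mRNAs 2 rose (4 adjusted over the list alone; adjusted p = 0.0041 with an estimated correlation). Ier3 fell by 0.85 ± 0.09. Hic1 (-0.46 ± 0.09), Tubb6 (-0.44 ± 0.08) and Tubb4b (-0.43 ± 0.08) were called as lower, but not without DMSO replicate 1 (adjusted p = 0.15, 0.094 and 0.19), DMSO replicate 4 (0.16, 0.12 and 0.16), halofuginone replicate 2 (0.18, 0.098 and 0.19) or halofuginone replicate 3 (0.3, 0.21 and 0.32), and Hic1 not with a replicate block (0.0504). Asns stood at 0.14 ± 0.10 (adjusted p = 0.7) and Txnip at 0.01 ± 0.08 (0.98). In all, 30 genes rose and 5 fell of 12535. The 35 calls became 16 without DMSO replicate 1, 15 without DMSO replicate 4, 21, 11 and 18 without halofuginone replicates 2, 3 and 4, and 85 with DESeq2.

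On polysomes halofuginone called 5 genes up and 1 down of 12223. Chac1 rose by 1.34 ± 0.16 (adjusted p = 0.00091) and Sesn2 by 0.98 ± 0.14. Slc1a4 (1.14 ± 0.19), Trib3 (0.94 ± 0.16) and Ier3 (-0.89 ± 0.14) were called with all libraries and each was lost without some: Slc1a4 without DMSO replicate 1 or 4 or halofuginone replicate 2 or 3 (adjusted p = 0.25, 0.21, 0.071 and 0.31), Trib3 without DMSO replicate 3 or 4 or halofuginone replicate 2 or 4 (0.087, 0.18, 0.069 and 0.094), and Ier3 without DMSO replicate 1 or 3 or halofuginone replicate 2 or 4 (0.15, 0.062, 0.069 and 0.094). The other called gene, the glutamine transporter gene Slc38a2 (0.88 ± 0.16), was named after its values were seen, and the alternatives were not run for it. ISR targets rose in 3 of 27 cases (16 adjusted over the list alone; adjusted p = 0.0003 with an estimated correlation). The 6 calls became 3 without DMSO replicate 1, DMSO replicate 4, halofuginone replicate 2 or halofuginone replicate 4, 1 when only the groups compared were fitted, where the calls on Sesn2, Slc1a4, Trib3 and Ier3 ended (adjusted p = 0.072, 0.08, 0.072 and 0.096), and 60 with DESeq2. Slc1a4 was also not called with a replicate block (0.053). For TE, edgeR's quasi-likelihood test called 0 of 12745 genes and DESeq2 called 0, and 675 genes had an unadjusted p below 0.05. Ribosomal protein mRNAs had a median TE change of -0.28, with 0 of 77 called (0 adjusted over the list alone; adjusted p = 0.87 with an estimated correlation).

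Torin1 asked what follows when mTOR is inhibited. In total RNA the death receptor gene Tnfrsf26 rose by 2.81 ± 0.09 (adjusted p = 3.4e-12), from 9.65 ± 0.843 to 67.9 ± 1.55 CPM, Fgl2 by 2.02 ± 0.14, Tmem140 by 2.01 ± 0.18 and Emp1 by 1.99 ± 0.16. Genes of naive and memory T cells rose in 11 of 16 cases and fell in 0, with a median of 0.64 (11 adjusted over the list alone; adjusted p = 0.02 with an estimated correlation): the chemokine receptor gene Ccr7 by 1.00 ± 0.11, Btg1 by 0.88 ± 0.08 and S1pr4 by 0.82 ± 0.08. ISR targets fell in 16 of 27 cases and rose in 0 (18 fell and 1 rose adjusted over the list alone; adjusted p = 0.01 with an estimated correlation), Chac1 by 1.77 ± 0.18, the mTORC1 inhibitor gene Ddit4 by 1.25 ± 0.09, Cebpb by 1.18 ± 0.11 and the leucine transporter gene Slc7a5 by 0.81 ± 0.08. Atf4 fell by 0.58 ± 0.06, and Ifng by 1.27 ± 0.10, from 818 ± 50.4 to 338 ± 41.9 CPM. Myc rose by 0.44 ± 0.09 and Txnip by 0.43 ± 0.08. Ribosome biogenesis genes fell in 14 of 25 cases (16 fell and 1 rose adjusted over the list alone; adjusted p = 0.31 with an estimated correlation), with Rrs1 at -0.74 ± 0.09. Ahdc1 (-1.76 ± 0.18), the GTPase gene Rrad (-1.75 ± 0.23) and Nol4l (-1.66 ± 0.22) were the other lowest genes. In all, 1671 genes rose and 1672 fell.

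On polysomes Torin1 raised Tnfrsf26 by 3.21 ± 0.26 (adjusted p = 1.8e-06), Klhl24 by 2.23 ± 0.23 and Fgl2 by 2.11 ± 0.34, and lowered Chac1 by 2.08 ± 0.18 (log2 fold change -2.08), Ahdc1 (-1.81 ± 0.27) and Hpdl (-1.78 ± 0.28). ISR targets fell in 13 of 27 cases (13 adjusted over the list alone; adjusted p = 0.0036 with an estimated correlation) and naive and memory genes rose in 10 of 16 and fell in 1 (14 and 1 adjusted over the list alone; adjusted p = 0.039 with an estimated correlation). The genes up and down were 1037 and 1014, and the total of 2051 became 1253, 1180 and 1349 without Torin1 replicates 1, 3 and 4.

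Torin1 lowered the TE of most ribosomal protein mRNAs. Of 77, 59 fell and 0 rose, with a median of -0.89 (70 fell adjusted over the list alone; adjusted p = 0.017 with an estimated correlation). Rps24 fell by 1.47 ± 0.19, Rpl7a by 1.36 ± 0.17, Rpl26 by 1.29 ± 0.18, Rpl32 by 1.28 ± 0.22 and Rpl10 by 1.19 ± 0.14 (adjusted p = 2.9e-05). Other TOP mRNAs fell in 11 of 19 cases (14 adjusted over the list alone; adjusted p = 0.0017 with an estimated correlation), Npm1 by 1.14 ± 0.15, Eef1b2 by 1.05 ± 0.16 and the initiation factor gene Eif3h by 0.91 ± 0.13, and the list was lower with Torin1 than with halofuginone (5 of 19 members, 14 adjusted over the list alone; adjusted p = 0.0069 with an estimated correlation). For ribosomal proteins that direct difference was lost (17 of 77 members, 63 adjusted over the list alone; adjusted p = 0.12 with an estimated correlation). Between Torin1 and 4EGI-1 neither list call held (ribosomal proteins adjusted p = 0.998 and other TOP mRNAs adjusted p = 0.32 with an estimated correlation). In all, 15 genes rose and 213 fell of 12745. Without DMSO replicate 1 or 3, or Torin1 replicate 1, 3 or 4, the 228 calls became 106, 107, 74, 85 and 140, and DESeq2 gave 392. The highest, Kmt2a (0.97 ± 0.23), Hectd4 (0.89 ± 0.18), Myo9a (0.81 ± 0.19) and Lyst (0.75 ± 0.17), were each not called without Torin1 replicate 1 (adjusted p = 0.22, 0.092, 0.071 and 0.14) or Torin1 replicate 3 (0.079, 0.0502, 0.145 and 0.14). Kmt2a, Myo9a and Lyst were also lost without DMSO replicate 1 (0.12, 0.12 and 0.094) or DMSO replicate 3 (0.14, 0.15 and 0.069), and Myo9a without Torin1 replicate 4 (0.058) or when only the groups compared were fitted (0.068).

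4EGI-1 asked what follows when eIF4E cannot bind eIF4G. In total RNA the lactase gene Lct rose by 6.43 ± 0.26 (adjusted p = 4.8e-11), from 0.213 ± 0.104 to 18.7 ± 3.16 CPM, the amine oxidase gene Aoc3 by 3.07 ± 0.23 and Tspoap1 by 2.84 ± 0.22. Effector genes fell in 10 of 18 cases (10 adjusted over the list alone; adjusted p = 0.093 with an estimated correlation). The chemokine gene Ccl4 fell by 3.84 ± 0.22, from 277 ± 60.5 to 19.4 ± 3.13 CPM, Ccl3 by 3.18 ± 0.22, Ifng by 1.53 ± 0.10 and Prf1 by 1.09 ± 0.09. Effector transcription factor genes fell in 7 of 16 cases and rose in 2 (8 and 2 adjusted over the list alone; adjusted p = 0.22 with an estimated correlation), Tbx21 (T-bet) by 1.17 ± 0.11 and Myc by 1.00 ± 0.09. The activation-induced gene Egr2 fell by 2.15 ± 0.14 and Slfn2 by 2.48 ± 0.12. ISR targets rose in 12 of 27 cases and fell in 2 (13 and 3 adjusted over the list alone; adjusted p = 0.15 with an estimated correlation), Ppp1r15a by 1.15 ± 0.09, Ddit3 by 0.89 ± 0.08 and Chac1 by 0.75 ± 0.14. Ribosome biogenesis genes fell in 14 of 25 cases (16 adjusted over the list alone; adjusted p = 0.31 with an estimated correlation), with Bop1 at -0.71 ± 0.07. In all, 1762 genes rose and 1546 fell.

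Mitochondrial transcripts changed in total and polysome RNA with 4EGI-1. The mitochondrial ribosomal RNA mt-Rnr1 rose in total RNA by 2.21 ± 0.17, to 4466 ± 898 CPM from 968 ± 229.8, and mitochondrial ribosomal RNA took 0.787% ± 0.177 of counts against 0.175% ± 0.0327 in DMSO. The labels call these libraries polyA RNA, so the counts cover only the mitochondrial ribosomal RNA that they took up. Mitochondrially encoded mRNAs fell in total RNA in 4 of 10 cases (5 adjusted over the list alone; adjusted p = 0.44 with an estimated correlation), with mt-Nd4 at -0.98 ± 0.14 and mt-Cytb at -0.97 ± 0.13. On polysomes all 10 fell, with a median of -2.87 (10 adjusted over the list alone; adjusted p = 0.081 with an estimated correlation). There mt-Nd4 fell by 4.32 ± 0.28 (adjusted p = 1.2e-08), from 831 ± 375 to 41.7 ± 10.2 CPM, and mt-Cytb by 4.17 ± 0.25. In TE 6 of 10 fell (8 adjusted over the list alone; adjusted p = 0.0032 with an estimated correlation), mt-Nd4 by 3.27 ± 0.32, mt-Cytb by 3.14 ± 0.29, mt-Nd2 by 2.61 ± 0.30 and mt-Co1 by 2.56 ± 0.35. The ribosomal RNA mt-Rnr1, named after its values were seen and not run under the alternatives, fell in TE by 2.43 ± 0.48 (adjusted p = 0.015), and mt-Rnr2 stood at -2.20 ± 0.64 (adjusted p = 0.092). In direct tests of TE the list was higher with halofuginone and with Torin1 than with 4EGI-1 (6 of 10 members in both; adjusted p = 0.00017 and 0.00076 with an estimated correlation).

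**Figure D4:**
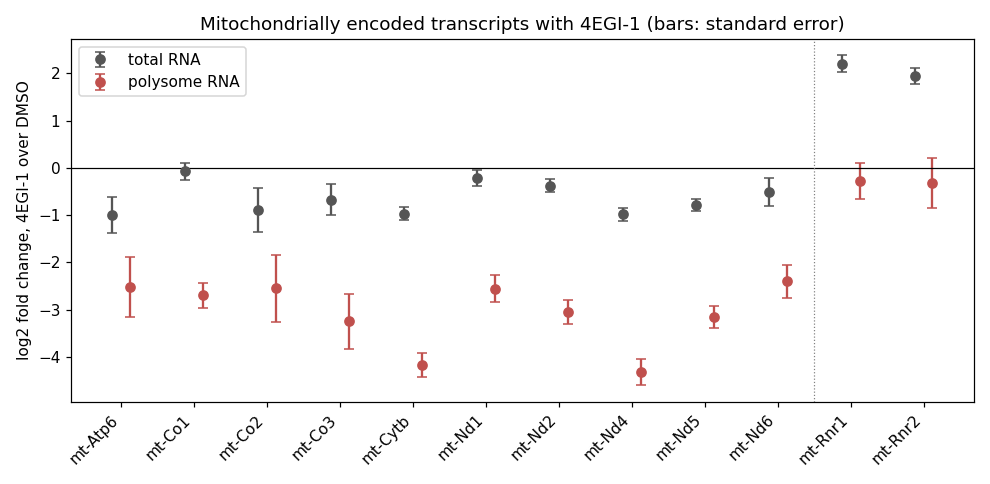
Log2 fold change with 4EGI-1 against DMSO, with standard error, of the 10 mitochondrially encoded mRNAs and of mt-Rnr1 and mt-Rnr2 in total RNA and in polysome RNA. On polysomes mt-Nd4 was at -4.32 ± 0.28, mt-Rnr1 at -0.28 ± 0.38 and mt-Rnr2 at -0.32 ± 0.53.

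The other polysome mRNAs that moved most with 4EGI-1 were Ccl4 (-4.21 ± 0.21, adjusted p = 5.7e-10), Tspoap1 (3.09 ± 0.22), Dzip3 (2.09 ± 0.27) and Arrdc3 (1.94 ± 0.21). Ribosomal protein mRNAs fell on polysomes in 74 of 77 cases, with a median of -0.78 (76 adjusted over the list alone; adjusted p = 0.28 with an estimated correlation), and replication histones in 14 of 18 (16 adjusted over the list alone; adjusted p = 0.28 with an estimated correlation), with H4c4 at -1.16 ± 0.21. In all, 1724 genes rose and 1773 fell, a share of 49.3% up that was 51.96% with RLE size factors. In TE 14 of 77 ribosomal protein mRNAs fell (74 adjusted over the list alone; adjusted p = 0.11 with an estimated correlation), with a median of -0.66. Ferritin mRNAs, named after their values were seen and not run under the alternatives, were also lower in TE, Fth1 by 1.63 ± 0.18 (adjusted p = 4.7e-06, log2 fold change -1.63) and Ftl1 by 1.16 ± 0.16 (log2 fold change -1.16). The TE calls were 36 up and 36 down, a share of 50% up that was 26.44% with RLE size factors. Their number, 72, became 29, 8 and 117 without DMSO replicates 1, 3 and 4, 13 and 9 without 4EGI-1 replicates 2 and 4, 630 with a lysate block, 9 when only the groups compared were fitted and 375 with DESeq2. The highest, Natd1 (a fold change of 2.83, adjusted p = 0.04), was lost without DMSO replicate 1 or 3 or 4EGI-1 replicate 3 or 4 (adjusted p = 0.089, 0.23, 0.11 and 0.15) and when only the groups compared were fitted (0.1). The next, Rnf24 (1.29 ± 0.30), Cep83os (1.23 ± 0.29) and Mmgt1 (1.16 ± 0.27) were lost without DMSO replicate 1 (adjusted p = 0.07, 0.11 and 0.088), DMSO replicate 3 (0.23, 0.23 and 0.25), 4EGI-1 replicate 2 (0.16, 0.16 and 0.13) or 4EGI-1 replicate 4 (0.18, 0.24 and 0.15), or when only the groups compared were fitted (0.092, 0.091 and 0.1). Rnf24 was also lost without DMSO replicate 4 (0.074), and Rnf24 and Cep83os with RLE size factors (0.051 for both).

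Whether the drugs differed from one another was tested directly. ISR targets in total RNA were higher with halofuginone than with Torin1 (22 of 27 members; adjusted p = 7.9e-05 with an estimated correlation) and lower with Torin1 than with 4EGI-1 (18 of 27; adjusted p = 0.0024 with an estimated correlation). Between halofuginone and 4EGI-1, 9 were higher with halofuginone and 4 lower, and the list was not called (adjusted p = 0.0905, and adjusted p = 0.41 with an estimated correlation). Myc was 1.44 ± 0.09 higher with Torin1 than with 4EGI-1 (adjusted p = 2.9e-09), 0.95 ± 0.09 higher with halofuginone than with 4EGI-1 and 0.49 ± 0.09 lower with halofuginone than with Torin1. Naive and memory genes were higher with Torin1 than with halofuginone (11 of 16; adjusted p = 0.017 with an estimated correlation) or 4EGI-1 (10 of 16; 0.041), and the list was not called between halofuginone and 4EGI-1 (adjusted p = 0.18, and 0.65 with an estimated correlation). Effector genes were higher with halofuginone than with 4EGI-1 (11 of 18; adjusted p = 0.032 with an estimated correlation), while the calls between halofuginone and Torin1 (7 higher and 3 lower) and between Torin1 and 4EGI-1 (13 higher) were lost (adjusted p = 0.57 and 0.22 with an estimated correlation). Torin1 and 4EGI-1 shared 395 genes up and 471 down in total RNA, where independent lists would share 234.9 and 206.2, and 380 genes went opposite ways. Both comparisons use the same DMSO libraries. Their fold changes correlated across genes at 0.122, and unchanged groups that share their controls gave 0.483 in simulation. The simulated groups hold no real effects, which widen fold changes and so dilute this correlation, so the values are not alike. The covariance of the fold changes was 0.0273, against 0.0225 in simulation.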

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

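The tests on scaling, short mRNAs, mitochondrial ribosomes and library type and the counts over other splits of the libraries were chosen only after the results were seen. The test on mitochondrial ribosomes was later extended to changes relative to total RNA, once its first value had been read. The test on scaling between Control and DMSO had first been set with RLE size factors, which were dropped because a factor for each library leaves a difference from the median of all genes unchanged.

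Polysome loading before any stress went opposite ways in the nutrient and drug experiments for 3 gene lists, with every Control lysate on one side of 0 and every DMSO lysate on the other. The differences were not tested. The lysate medians of polysome over total RNA for ribosomal protein mRNAs ran from -0.929 to -0.865 in Control and from 0.138 to 0.542 in DMSO, a difference of means of -1.22. For naive and memory genes they ran from 0.194 to 0.375 and from -0.54 to -0.167 (difference 0.667), and for effector transcription factors from 0.166 to 0.423 and from -0.366 to -0.0732 (difference 0.536). Scaling alone is argued against for ribosomal proteins, since relative to the median of all genes, which a factor for each library moves as much as the list, the difference was -1.37. A difference in library type stays open and cannot be told apart from the experiment: summed replication histone levels in total RNA were 2342 ± 54.7 CPM in Control and 64.26 ± 5.21 CPM in DMSO (18 genes, 3 libraries each), a ratio of 36.5, and no library was made both ways. No biological explanation was tested.

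In translational efficiency, 29 to 72 of 78 ribosomal protein mRNAs fell in each deprivation and 59 of 77 with Torin1. The list median was also below 0 with halofuginone and 4EGI-1, which the tests of this paragraph leave out. Direct list calls of Torin1 against 4EGI-1 and halofuginone did not hold with an estimated correlation (adjusted p = 0.998 and 0.12). The list call held with an estimated correlation without glucose and with Torin1 (adjusted p = 0.039 and 0.017), and was lost without arginine, BCAA, glutamine and methionine (0.12, 0.69, 0.73 and 0.61). Scaling alone is argued against: relative to all genes, the list median was at most -0.154 over the 6 comparisons. Of 10000 random lists matched on abundance and starting polysome load, 0% had a median as low in any of the 6. The genes of these lists were drawn independently, while ribosomal protein mRNAs vary together (estimated correlation 0.73 in TE of the drug experiment). Medians of the random lists therefore spread too little, and the share cannot decide on abundance and starting load. The matching was incomplete, with a mean log2 CPM of 9.68 for the list and 8.76 for its matches (Torin1: 10.4 and 9.93) and a mean starting load of -1.06 and -0.922 (Torin1: 0.226 and 0.271). Abundance and starting load thus stay open, most of all without BCAA, where the list median of -0.28 lay close to the lowest matched one, -0.255. A slide of short mRNAs below the pooled fractions stays open and may account for part or all of the fall. The mostly short nuclear mRNAs of oxidative phosphorylation were also lower in all 6, with list medians of at most -0.317 relative to all genes. Without BCAA that was further down than the ribosomal protein list at -0.154, so no fall particular to ribosomal proteins is shown there. The lengths of mRNAs were not used here.

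All 10 mitochondrially encoded mRNAs fell on polysomes with 4EGI-1, though the list call was lost with an estimated correlation (adjusted p = 0.081). Among them mt-Atp6, mt-Co2 and mt-Co3 had few counts. Scaling is argued against by a list median of -2.87 relative to all genes, and 1 deviating library by a median of -2.41 or lower in each fit that left out 1 library. Loss of whole mitochondria or of their ribosomes from the pooled fractions stays open. On polysomes the lower of mt-Rnr1 and mt-Rnr2 was at -0.323, against -2.87 for the mRNAs, but relative to total RNA, where mt-Rnr1 rose by 2.21 ± 0.17, mt-Rnr1 was at -2.43 ± 0.48 and mt-Rnr2 at -2.20 ± 0.64, against a median of -2.39 for the mRNAs. These libraries are labelled polyA RNA, and how much of each ribosomal RNA they took up was not measured. An effect of 4EGI-1 on mitochondrial translation also stays open, as untested.

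Each comparison of 3 with 3 libraries allows 10 splits, too few for a share under 0.05. Every split but the real one mixes both groups, so a real difference enters the spread within groups and pushes the counts towards 0. Low counts in the other splits are thus no separate support for the real ones. In 25 of the 26 comparisons the highest count of the other 9 splits was 0, against real counts from 6 (polysome RNA, halofuginone) to 8583 (polysome over total, Control), so 1 split of 10 gave as many. For TE with halofuginone all 10 splits gave 0 calls with edgeR's quasi-likelihood test, where DESeq2 also called 0 and 675 genes had an unadjusted p below 0.05.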

How the results depend on the processing

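The fit without the entries derived from ribosomal RNA (Rn18s-rs5, Lars2, Mir6236, mt-Rnr1 and mt-Rnr2) was chosen only after their shares had been seen. Of 3332 results for named genes, 37540 of 39130 values under the alternatives kept direction and side of the threshold, 1192 became weaker, 398 stronger and 0 reversed. Of 796 list results, 8839 of 9360 values did so, 339 became weaker, 181 stronger and 1 reversed: immediate early genes in total RNA with halofuginone had a median of 0.17483 with the replicate block (adjusted p = 0.0086). Of 306 alternative counts 267 stayed within 1.5 times the first and 39 did not. RLE size factors, no filter on low counts and leaving out the entries derived from ribosomal RNA moved none of the 26 counts that far. With 1 library left out at a time, counts ran from 617 to 1243 (total RNA, arginine), 526 to 2903 (TE, arginine), 2168 to 3260 (TE, glucose), 11 to 35 (total RNA, halofuginone), 3 to 4 (polysome, halofuginone), 1180 to 1740 (polysome, Torin1), 74 to 242 (TE, Torin1) and 8 to 117 (TE, 4EGI-1), where the library numbers are smaller by construction and the pair of libraries left is assumed to vary like the other groups. DESeq2 gave 85 (total RNA, halofuginone), 60 (polysome, halofuginone), 392 (TE, Torin1) and 375 (TE, 4EGI-1). Fitting only the groups compared gave 1326 (TE, arginine), 1 (polysome, halofuginone) and 9 (TE, 4EGI-1), and the lysate block 630 (TE, 4EGI-1). For DESeq2, for the groups compared and for the block the cause was not tested. With an estimated correlation 52 of 275 list calls held. Among genes with a mean log2 CPM of at least 4 the median correlation between conditions was 0.671 in total RNA, 0.8 in polysome RNA and 0.848 in TE of the nutrient experiment, and 0.308 in total RNA of the drug experiment, against 0.58, 0.715, 0.637 and 0.264 over all genes. The spike-in alternative could not run, since the table has no spike-in entry, and the pseudocount alternative does not apply to counts. Depth and replicate number limit small changes: of simulated changes of 1.5-fold, 62.7% were recovered in total RNA without arginine, 55.2% in TE without arginine, 29.9% on polysomes with halofuginone and 17.9% in TE with halofuginone, and of changes of 4-fold 97%, 87.9%, 87.9% and 92.4%.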

Other observations

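The test on the genes that rose with halofuginone was set before its result was seen. The correlations and the overlaps in TE between the drug and nutrient experiments were chosen later.

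Several gene lists moved in ways that the comparisons above leave out. Interferon response genes rose in total RNA without glutamine in 7 of 14 cases (median 0.51; 7 adjusted over the list alone; adjusted p = 0.089 with an estimated correlation) and fell with 4EGI-1 in 6 of 14 (median -0.64; 6 adjusted over the list alone; adjusted p = 0.25 with an estimated correlation). The p53 targets rose without glutamine in 7 of 16 cases and fell in 3 (7 and 4 adjusted over the list alone; adjusted p = 0.043 with an estimated correlation), with Gadd45a up by 2.56 ± 0.12, Plk2 by 1.58 ± 0.06 and Cdkn1a down (-0.71 ± 0.08). Polyamine genes fell without arginine in 2 of 9 cases (2 adjusted over the list alone; adjusted p = 0.032 with an estimated correlation), Amd1, which decarboxylates S-adenosylmethionine, by 0.46 ± 0.07, and Amd1 fell by 1.49 ± 0.08 without glucose. ER stress genes rose on polysomes without arginine in 11 of 19 cases and fell in 1 (median 0.32; 11 and 4 adjusted over the list alone; adjusted p = 0.56 with an estimated correlation). Heat shock genes fell in total RNA without BCAA in 8 of 15 cases (8 adjusted over the list alone; adjusted p = 0.1 with an estimated correlation), Hspa8 by 0.41 ± 0.07. With Torin1, lysosome genes rose in 7 of 21 cases and fell in 1 (9 and 1 adjusted over the list alone), NRF2 targets fell in 5 of 13 and rose in 1 (5 and 1), and one-carbon genes fell in 7 of 16 and rose in 1 (8 and 2; adjusted p = 0.31 for each of these with an estimated correlation). Mat2a rose without methionine by 1.01 ± 0.08 and fell by 0.72 ± 0.08, 0.96 ± 0.08, 1.77 ± 0.08 and 1.06 ± 0.08 without arginine, BCAA, glucose and glutamine.

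Marker levels and changes alone do not give cell make-up. Ranges pool fractions and library types. Over the 60 libraries Cd8a ran from 82.28 to 727.7 CPM. The regulatory T cell gene Foxp3 ran from 0 to 2.756 and the helper T cell gene Zbtb7b from 5.494 to 24.87. Of B-cell genes Cd79a ran from 0 to 0.5994, Ighm from 8.02 to 136.4, H2-Ab1 from 52.14 to 136.3 and H2-Aa from 0.05375 to 1.288. Of myeloid genes Fcer1g ran from 0 to 2.017 and Cd68 from 3.722 to 15.92. The NK and erythroid marker lists had 0 of 5 members each in the table. On polysomes the CD8 T cell markers fell in 5, 6, 5 and 7 of 9 cases without BCAA, glucose, glutamine and methionine (5, 6, 5 and 7 adjusted over the list alone; adjusted p from 0.47 to 0.49 with an estimated correlation), and both measured CD4 T cell markers, Zbtb7b and Ikzf4, rose without BCAA (1.28 and 0.52; adjusted p = 0.23 with an estimated correlation), glutamine (1.51 and 0.58; 0.22) and methionine (1.02 and 0.47; 0.47). Without glucose Zbtb7b rose by 1.01 and Ikzf4 stood at -0.01 (0.62), and without arginine they stood at -0.06 and 0.18 (0.84). Of 4 B cell markers 2 fell in total RNA without glutamine (adjusted p = 0.86 with an estimated correlation), and of 2 myeloid markers 1 fell in TE without glutamine (adjusted p = 0.96 with an estimated correlation).

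Genes that rose with halofuginone may belong to the response to missing amino acids. The lowest share of the 30 genes that also rose under an amino acid deprivation was 83.3%, without arginine (25 genes, where independent lists would share 1.59). It was 30 genes without BCAA, 29 without glutamine and 28 without methionine, where 1 fell. Without glucose 28 rose and 2 fell, so the response is not particular to amino acids. Across the 27 ISR targets in total RNA the fold changes with halofuginone correlated with those of the deprivations at 0.572 to 0.809, those with 4EGI-1 at 0.325 to 0.429 and those with Torin1 at -0.393 to -0.175, across genes that are not independent replicates. A positive correlation was thus not particular to halofuginone. On polysomes these ranges were 0.401 to 0.623, 0.0466 to 0.184 and -0.135 to 0.267, and in TE 0.168 to 0.59, 0.293 to 0.533 and 0.272 to 0.493. Across all genes in total RNA they were 0.136 to 0.222, 0.0316 to 0.074 and 0.17 to 0.338, and across genes with a log2 CPM of at least 4 they were 0.246 to 0.431, 0.0349 to 0.224 and 0.184 to 0.407. With that limit the order of halofuginone and Torin1 turned without arginine, BCAA and glutamine. Genes that fell in TE with Torin1 and also without arginine, BCAA, glucose, glutamine and methionine numbered 136, 99, 195, 140 and 151, where independent lists would share 21.9, 42.2, 37.9, 56.4 and 66.6. With 4EGI-1 they numbered 22, 15, 23, 16 and 24, where independent lists would share 3.71, 7.16, 6.43, 9.58 and 11.3. An excess was thus not particular to Torin1. The genes that fell with Torin1 include ribosomal protein mRNAs described above.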
